A study of Saccharomyces cerevisiae with 68 samples.

How the data were processed

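Cultures of 100 mL were grown in YPD at 30 °C to an OD600 of 0.8 and labelled for 6 min with 5 mM 4-thiouracil. Labelled S. pombe cells grown at 31 °C were mixed in before RNA extraction, at 3 S. cerevisiae cells for each of S. pombe. From 200 µg of the total RNA, labelled RNA was biotinylated and purified, and cRNA for the Affymetrix arrays was prepared from 150 ng, all per the labels' protocols. All strains derive from FY406, and the labels state 2 independent biological replicates of each deletion strain, where 4 arrays were deposited for 5 of the 8 strains. Whether these are repeats of 2 cultures is not given in the sources used here.

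The 68 deposited columns hold array intensity values on a linear scale for 10928 probe sets, made with Affymetrix Expression Console 1.4.1 per the submitters' processing notes. Algorithm, masks for the species and any scaling to S. pombe are not given in the sources used here. In 58 arrays the mean of all probe sets, without 2% at each end, was within 1 of 100, so each array had been scaled as a whole. The 10 others are WT nascent replicates 1 and 2 and the nascent arrays of spt7 and ubp8_gcn5. WT total replicates 1 and 2 equal the means of replicates 3 and 4 and of 5 and 6 in all 5498 S. cerevisiae and 1746 S. pombe probe sets (tolerance 1e-06). WT nascent replicates 1 and 2 equal such means for S. pombe but for only 267 S. cerevisiae probe sets, with median ratios of 2.24 and 2.00. WT replicates 1 and 2 of both fractions were therefore left out. In the spt7 nascent arrays, multiplying S. cerevisiae values by 2.5 brings the trimmed mean to 98.6 to 98.7. In ubp8_gcn5 nascent arrays, 1.85 for 2869 probe sets and 2.4975 for 2629 (a ratio of 1.35, log2 0.433) bring it to 97.7 to 97.8. Values were used as deposited, and with these constants undone as an alternative. The order of S. cerevisiae genes in the spt7 nascent arrays was unrelated to that of the same strain's total RNA (rho = 0.0182 to 0.0207, S. pombe 0.988 to 0.993), so they entered only the tests of array medians, and spt20 and spt7 were compared in total RNA.

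Species and genes were read from the probe annotation, with 7244 probe sets for 1 gene, 1 for several and 3683 without a name, and 12 symbols were updated. For the 47 S. cerevisiae genes with several probe sets the brightest was used. The lowest 25% of genes by mean log2 signal in a fraction were left out in each species, leaving 4086 S. cerevisiae genes (4016 between fractions) and 1305 S. pombe genes. Spike-scaled values are log2 signals minus the array's median over S. pombe genes, and relative values are centred on the array's median over S. cerevisiae genes. Arrays fell into 2 batches by the correlation of their S. pombe profiles, 30 arrays and 4 (WT replicates 7 and 8 and spt3_gcn5) in each fraction, with mean rho between them of 0.669 in nascent and 0.851 in total RNA and of at least 0.962 within.

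Gene tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes) over 28 nascent or 32 total arrays, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Differences of nascent and total changes, of double and single mutants and of double mutants from the sum of the singles were contrasts of the same fits. One median per array was compared by two-sided exact permutation tests, with adjustment over 16 shifts against WT. The smallest p these can give is 0.00476 for 4 against 6 arrays, 0.0357 for 2 against 6, 0.0286 for 4 against 4, 0.0667 for 2 against 4 and 0.333 for 2 against 2. Of 30 gene lists fixed beforehand, 27 were tested with camera at a preset correlation of 0.01, and 144 of 405 tests passed, 2 of them also with an estimated correlation. Lists of alpha-specific and of meiosis and sporulation genes had fewer than 3 tested genes, and the list of Ty genes was not analysed here. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

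Genes named in the text are the deleted ones and, among genes past the threshold in the relative fit whose mutant arrays all lie outside the WT range, those with the largest rises and falls. These were 8 each way in nascent and 5 in total RNA, and 4 each way without the range condition between mutants or fractions. The rule also allows up to 4 members of a list with the lowest p, which are counted here instead of named. The fits were tested on simulated data with 200 of 4086 genes changed. At log2 sizes of 0.5, 1 and 2 they recovered 53.7, 85.1 and 100% in spt20, 41.8, 89.6 and 98.5% in ubp8, 50.7, 86.6 and 98.5% in gcn5, 29.9, 76.1 and 97% in spt3, 25.4, 85.1 and 98.5% in spt8, 43.3, 88.1 and 98.5% in ubp8_gcn5 and 29.9, 79.1 and 97% in spt3_gcn5, with 3 to 11 false calls among 141 to 167. S. pombe control genes passed at 0 to 53.6% in the nascent fits, so these false calls do not carry over to every strain. The signals hold no background value, and the spread between arrays sets the precision.

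Alternatives were no spike-in scaling, scaling by the brightest 25% of S. pombe genes, quantile normalization, no signal filter, one that leaves out 50%, the mean of a gene's probe sets, averages of consecutive replicate numbers, a trend in eBayes, fits of the compared groups only, replicate number or culture as a block, and leaving out each array. Added later were WT replicates 1 and 2 as deposited, constants undone (for spt7 also without the filter), batch as a block, WT arrays of the same batch, leaving out the arrays labelled spt20 total replicates 1 and 3, and the SAGA list without deleted genes. Promoters with a TATA box were not analysed, as the reference holds no genome sequence.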

Results

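Newly synthesised RNA, labelled for 6 min with 4-thiouracil and purified, and total RNA were measured on yeast arrays in a wild type (WT) and 8 strains lacking subunits of SAGA, the coactivator complex that carries the Gcn5 acetyltransferase, the Ubp8 deubiquitinase and the TBP-contacting subunits Spt3 and Spt8. Spt20 and Spt7 hold the complex together, and 2 strains lacked a pair of subunits. S. pombe cells, mixed in at 1 for every 3 S. cerevisiae cells, gave a reference for changes of all transcripts at once. Each fraction held 34 arrays: 8 WT, of which 6 were used, 4 each of spt20, spt7, ubp8, gcn5 and ubp8_gcn5, and 2 each of spt3, spt8 and spt3_gcn5. The arrays carry no read depth, and their number limits the precision. Changes are log2 values against WT ± standard error of the limma fit over 4086 genes, or over all genes for UBP8 and GCN5, which the signal filter leaves out. They are spike-scaled when set against the S. pombe genes, and relative when set against the median of all S. cerevisiae genes. By their S. pombe profiles, WT replicates 7 and 8 and both spt3_gcn5 arrays form a second batch, so values with batch as a block (called blocked) are given beside many sizes it moves, and counts it moves and signs it turns in the closing section. Counts called fitted alone come from a fit of the compared groups only, and averaged ones from means of consecutive replicates.

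The deleted genes check the strain labels, and since they lie at the floor of the arrays their sizes are imprecise. In nascent RNA the spike-scaled change was -7.41 ± 0.57 for SPT20 in spt20, -7.88 ± 0.44 for UBP8 in ubp8 and -5.12 ± 0.48 for GCN5 in gcn5 (n = 4 against 6). SPT3 changed by -7.81 ± 0.29 in spt3 and SPT8 by -7.37 ± 0.40 in spt8 (n = 2 against 6). Both genes were lost in each double mutant, with -5.58 ± 0.44 for UBP8 and -6.48 ± 0.48 for GCN5 in ubp8_gcn5, and -9.33 ± 0.29 for SPT3 and -8.21 ± 0.61 for GCN5 in spt3_gcn5. In total RNA, SPT7, UBP8, GCN5, SPT3 and SPT8 lay below every WT array in each array of the strains that lack them. In total RNA of spt20, SPT20 changed by -3.20 ± 0.96 spike-scaled, which did not pass (adjusted p = 0.0544), and by -3.44 ± 0.85 relative, which did (adjusted p = 0.00352). Its deposited log2 signal was 6.02 and 6.32 in the arrays labelled spt20 total replicates 1 and 3 against -0.27 and -1.15 in replicates 2 and 4, and, spike-scaled, reached 1.92 where WT arrays lay between 0.43 and 0.95. The S. cerevisiae rows of the spt7 nascent arrays were out of order against the array's own total RNA, so no gene of that group is reported and the signal filter does not hold for its medians. Yet their SPT7 row lay at -5.73 to -5.01 spike-scaled, among the lowest 0.18 to 0.31% of rows in all 4 arrays, as the deletion predicts and a plain shuffle would rarely give.

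Did loss of SAGA subunits lower the transcription of most genes? The median spike-scaled log2 signal of nascent RNA was 1.81 ± 0.58 in WT (SD, n = 6). It lay below every WT array in all 4 arrays of spt20 (-1.14, 45.5% of WT), spt7 (-2.74, 14.9%; -2.21, 21.5%, without the signal filter) and ubp8_gcn5 (-1.80, 28.7%). After Benjamini-Hochberg adjustment over the 16 shifts, two-sided exact permutation tests gave adjusted p = 0.0381 for both spt7 and ubp8_gcn5 and 0.0762 for spt20. Deposited S. cerevisiae signals of these spt7 and ubp8_gcn5 arrays appear divided by constants (1 in spt7, 2 in ubp8_gcn5), and with the constants undone the shifts were -0.90 in spt7 without the filter (-1.43 with it) and -0.56 in ubp8_gcn5, none of which passed (exact adjusted p = 0.143, 0.0762 and 0.267). Without any 1 of the strain's or the WT nascent arrays, against WT arrays of the same batch and with consecutive replicates averaged, too few arrays are left to pass unless several shifts share the smallest p, and the shifts were -2.89 to -2.61, -2.43 and -2.73 in spt7 and -1.92 to -1.66, -1.48 and -1.78 in ubp8_gcn5. Scaled by the brightest 25% of S. pombe genes, ubp8_gcn5 was -2.03 and did not pass (exact adjusted p = 0.0914). With 2 arrays, spt3 (-1.09, exact adjusted p = 0.143) and spt3_gcn5 (-2.60, 16.5% of WT, exact adjusted p = 0.114) did not pass, where the smallest exact p possible is 0.0357. Shifts of ubp8 (-0.30), gcn5 (-0.46) and spt8 (0.19; -0.020 with WT replicates 1 and 2) did not pass (exact adjusted p = 0.457, 0.282 and 0.714). Against WT arrays of the same batch the shifts were 0.016 in ubp8, -0.15 in gcn5, 0.50 in spt8, -0.78 in spt3, -3.23 in spt3_gcn5 and -0.82 in spt20.

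In total RNA no strain passed. The shift was -1.59 in spt3_gcn5 (33.2% of WT, exact adjusted p = 0.114), -0.53 in spt7 (exact adjusted p = 0.143; -0.52 and past the threshold by the brightest 25% of S. pombe genes) and 0.58 in spt8 (-0.021 without spike-in scaling). The others were 0.36 in ubp8, 0.25 in gcn5, -0.084 in spt3 (0.018 without WT total replicate 6), -0.27 in ubp8_gcn5, and 0.24 in spt20, which turned to -0.57 without spt20 total replicates 1 and 3. Against WT arrays of the same batch they were -1.09 in spt3_gcn5, -0.78 in spt7, 0.33 in spt8, 0.11 in ubp8, -0.0033 in gcn5, -0.33 in spt3, -0.52 in ubp8_gcn5 and -0.014 in spt20.

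**Figure D1:**
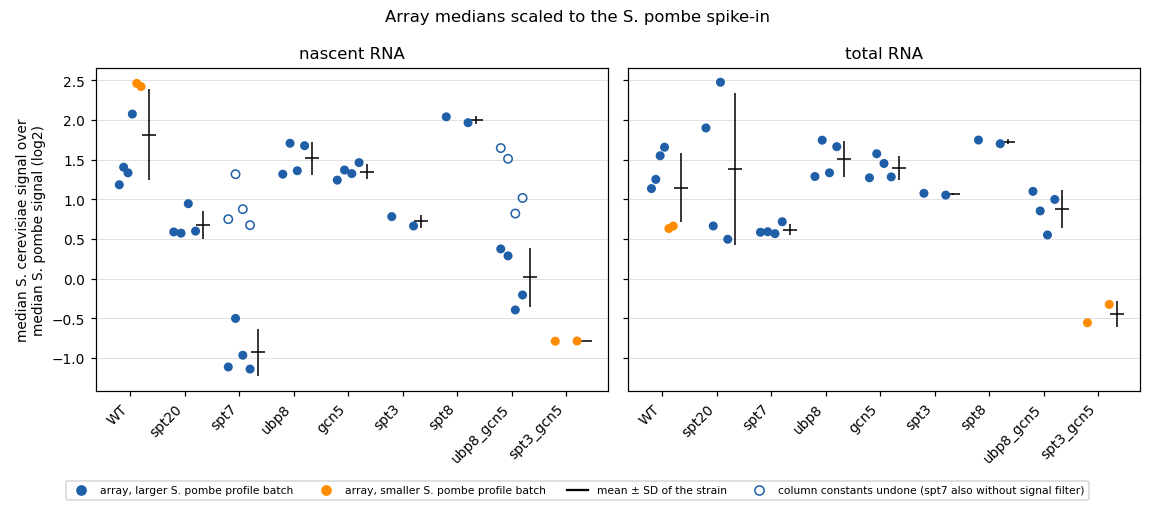
Median spike-scaled log2 signal of each array (points) with strain means (bars), nascent and total RNA, by strain. The 6 WT arrays lie between 1.18 and 2.46 in nascent RNA, above all spt20 arrays, which lie between 0.57 and 0.94.

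Without Spt20, nascent RNA of PHO84, the high-affinity phosphate transporter, changed by -4.70 ± 0.29, the mannoprotein gene CWP1 by -3.91 ± 0.12 and the acid phosphatase gene PHO3 by -3.21 ± 0.17 (n = 4 against 6). DIP5 and TAT1, amino acid permeases, INA1 and MRH1 changed by -2.55 to -2.90. Higher were HUG1, a target of the DNA damage checkpoint (3.42 ± 0.73; 2.03 blocked), ARG1 of arginine synthesis (2.23 ± 0.15) and the chaperone gene HSP26 (2.22 ± 0.39), with ATG10, HBN1, YLL056C and MHT1 at 2.27 to 2.83 (HBN1 0.59 blocked) and THI13, uncertain because near-identical genes share its probes, also higher. Of 14 cell separation genes, 11 fell, 0 rose and 3 did not pass (median -1.11, adjusted p = 3.3e-06 at the preset correlation of genes, 0.323 at an estimated one), and adjusted over the list alone (list-wide) 12 fell and 0 rose. Among 55 mitochondrial ribosomal protein genes, 23 fell, 2 rose and 30 did not pass (median -0.23, adjusted p = 0.00298, estimated 0.534), as list-wide. Of 5 hexose transporter genes, 4 fell, 0 rose and 1 did not pass (median -1.81, adjusted p = 0.00331, estimated 0.362), as list-wide. In all, 1861 genes passed relative to the others, 968 higher and 893 lower (1886 blocked, 942 fitted alone, 770 averaged, 202 with replicate number as a block), and 3456 spike-scaled, 34 higher and 3422 lower (165 with that last block). In total RNA, TMA10 (1.77 ± 0.20), HUG1, TPM2 and TEN1 were higher, and YRO2 (-2.16 ± 0.35), TAT1, YGP1 and MRH1 lower. Without spt20 total replicates 1 and 3, which carry SPT20 signal, YRO2 was -3.38 and TAT1 -3.23 (from -1.94). Naming used all 4 arrays and left out PHO84 and CWP1. In replicates 2 and 4 these lay at -5.455 and -5.27, and -4.45 and -4.26, from WT 3 to 6, and did not fall in 1 and 3. Total RNA had 1556 relative calls (7 fitted alone, 449 averaged, 34 with replicate number as a block) and 64 spike-scaled (2196 without replicates 1 and 3, 390 without 4).

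In spt7, reported in total RNA, PHO84 changed by -5.35 ± 0.72, CWP1 by -4.56 ± 0.61 and PHO3 by -3.95 ± 0.41 (n = 4 against 6), and the hexose transporter gene HXT7, whose probes HXT6 shares, was lower. ARG1 (3.65 ± 0.32), HUG1 (2.58 ± 0.30) and SPG5 (2.04 ± 0.33) were higher, with THI13 and DDI3, each read by shared probes. Among 21 general stress response genes, 9 fell, 0 rose and 12 did not pass (median -0.71, adjusted p = 5.4e-05, estimated 0.522), while list-wide 12 fell and 0 rose. In 16 sulphur and methionine genes, 11 rose, 0 fell and 5 did not pass (median 0.93, adjusted p = 5.4e-05, estimated 0.457), and list-wide 12 rose and 0 fell. Of 22 G1/S cell cycle genes, 9 fell, 0 rose and 13 did not pass (median -0.22, adjusted p = 0.00408, estimated 0.522, 0.0831 blocked), as list-wide. Relative to other genes 1810 passed, 907 higher and 903 lower (1036 fitted alone, 985 averaged), and spike-scaled 1136, 32 higher and 1104 lower. The spike-scaled count was 2573 blocked, and 566, 604 and 575 without spt7 replicates 1, 2 and 3 and 704 and 643 without WT replicates 5 and 6.

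Without the deubiquitinase (ubp8), nascent HSP26 (2.00 ± 0.39; 1.30 blocked), YML131W (1.53 ± 0.51; 0.45), YHI9, CPD1, YPR172W and YMR090W (1.42 to 1.46; 0.55 to 0.72) rose, as did SOR2 on shared probes. HUG1 rose by 2.44 ± 0.73, but 1.05 when blocked, which did not pass (adjusted p = 0.0630). FSH2 (-1.17 ± 0.093), the exporter gene AQR1 (-1.14 ± 0.19, n = 4 against 6) and THI7, the thiamine transporter, were lowest, followed by FCY2, NOG1, MDH2, TAT1 (not past the threshold when blocked) and, on shared probes, HXT7. Of 93 ribosome biogenesis genes, 41 fell, 0 rose and 52 did not pass (median -0.34, adjusted p = 3.8e-15, estimated 0.298), and list-wide 53 fell and 0 rose. Among 12 G2/M cell cycle genes, 5 fell, 0 rose and 7 did not pass (median -0.46, adjusted p = 1.3e-04, estimated 0.486), while list-wide 9 fell and 0 rose. In 6 seripauperin genes, 4 rose, 0 fell and 2 did not pass (median 0.69, adjusted p = 0.0149, estimated 0.486, 0.221 blocked), and list-wide 4 rose and 0 fell. Nascent calls numbered 549 relative, 273 higher and 276 lower, and 6 spike-scaled, 4 higher and 2 lower (480 and 47 blocked). The relative count was 39 fitted alone, 1 averaged, 52 with replicate number as a block, 224 without ubp8 replicate 4 and 1026 without WT replicate 4, and the spike-scaled count 0 without ubp8 replicate 2 or 4 and 157 without WT replicate 5. Total RNA had 820 relative calls (93 fitted alone, 112 averaged, 495 without replicate 3) and 31 spike-scaled, 31 higher and 0 lower (4 without replicate 2). Its leading genes were OYE3 (2.47 ± 0.88; 0.48 and not past the threshold when blocked), HBN1 (2.21 ± 0.74; likewise 0.58), HUG1, SOR2 and THI4 of thiamine synthesis (1.44 ± 0.14) upward, and THI7 (-1.16 ± 0.13), FSH2, AQR1, ECL1 and TEC1 downward.

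In gcn5, nascent PHO84 changed by -3.75 ± 0.29, VTC3 of polyphosphate synthesis by -2.43 ± 0.15, the a-factor gene MFA1 by -2.32 ± 0.19 and BAR1, whose protease cleaves alpha factor, by -1.83 ± 0.21 (n = 4 against 6). PHO3, YDR222W and SPR6 changed by -1.67 to -1.76, and PHO11 fell on shared probes. ARG1 rose by 3.22 ± 0.15 and CYC7, a cytochrome c gene, by 1.80 ± 0.25, with CIS1, CRG1, YER053C-A and RTS3 at 1.86 to 2.14 (CIS1 1.13 and YER053C-A 0.93 blocked) and IMA3 and THI13 higher on shared probes. Of 11 phosphate genes, 10 fell, 0 rose and 1 did not pass (median -1.33, adjusted p = 1.8e-16, estimated 0.0114), as list-wide. Among 14 mating and pheromone response genes, 10 fell, 0 rose and 4 did not pass (median -0.87, adjusted p = 1.9e-08, estimated 0.0114), while list-wide 11 fell and 0 rose. In 40 amino acid biosynthesis genes, 11 rose, 3 fell and 26 did not pass (median 0.20, adjusted p = 0.0112, estimated 0.806, called in 8 of 10 fits without 1 array, spike-scaled median -0.26), as list-wide. Relative calls were 823, 410 higher and 413 lower (198 fitted alone, 142 averaged, and 1432 blocked, where S. pombe genes passed about as often), and spike-scaled calls 717, 27 higher and 690 lower (25 fitted alone, 9 averaged). The spike-scaled count ran from 266 without gcn5 replicate 3 to 1659 without WT replicate 3. In total RNA, ARG1 (3.45 ± 0.32), CIS1 and YER053C-A were higher, OYE3 was higher by 2.33 ± 0.88 but 0.35 and not past the threshold when blocked, and PHO84 (-4.24 ± 0.72), MFA1, VTC3 and BAR1 were lower. Total RNA gave 1314 relative (499 fitted alone, 574 averaged) and 104 spike-scaled calls, 90 higher and 14 lower (49 without replicate 2, 220 without WT replicate 6).

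**Figure D2:**
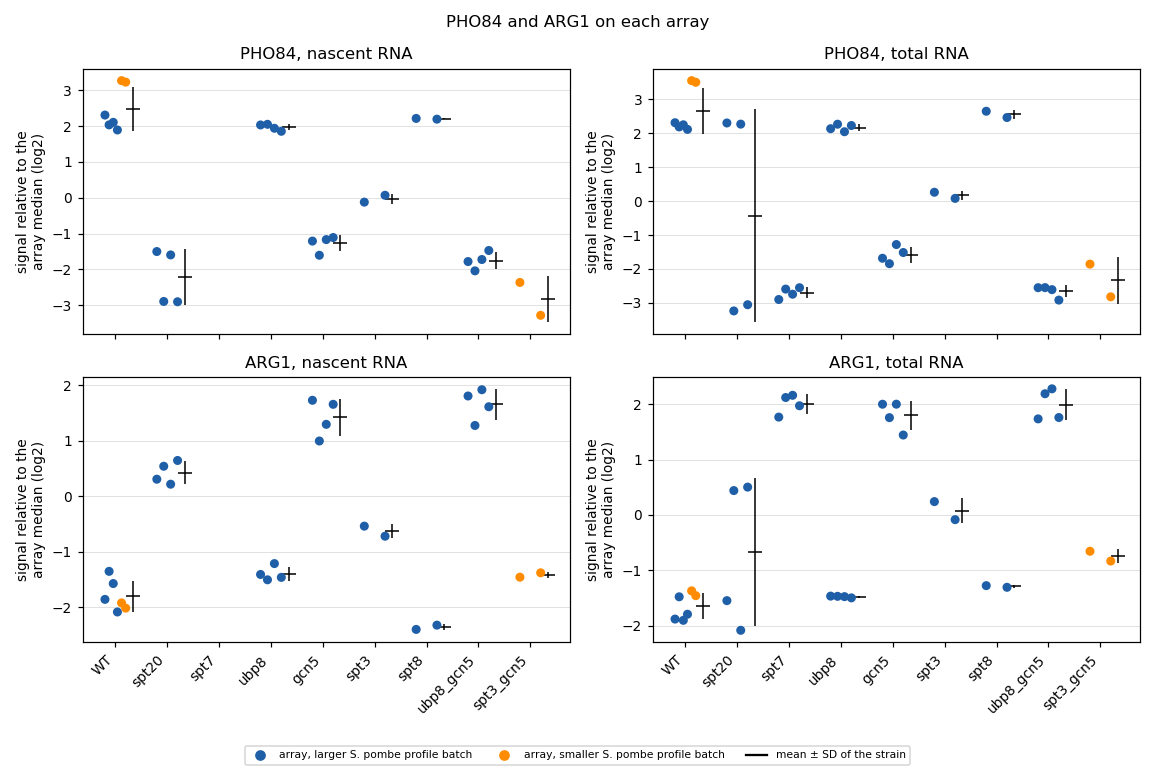
Log2 signal of PHO84 and ARG1 relative to each array's median, by strain and fraction, with strain means. Nascent PHO84 lies between -2.90 and -1.50 in spt20, and nascent ARG1 between 0.99 and 1.73 in gcn5.

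In spt3, nascent RNA of FET3, an iron oxidase gene, changed by -3.27 ± 0.26, the mannoprotein gene TIR3 by -2.87 ± 0.30, the repressible acid phosphatase gene PHO5 by -2.74 ± 0.33 and PRY1 by -2.53 ± 0.24 (n = 2 against 6). PRM7, PHO84 and FIT2 changed by -2.47 to -2.63. SER3 of serine synthesis rose by 1.65 ± 0.24, and CIN5, DAD2, MRS4, TMA10 and YMR030W-A by 1.28 to 1.75, beside IMA3 and YOR072W-B on shared probes. Of 14 iron regulon genes, 6 fell, 0 rose and 8 did not pass (median -0.38, adjusted p = 2.7e-06, estimated 0.0541), as list-wide. Of 17 model promoter genes of SAGA studies, 6 fell, 1 rose and 10 did not pass (median -0.71, adjusted p = 0.00115, estimated 0.0919), and list-wide 9 fell and 2 rose. Among 14 cell separation genes in total RNA, 12 fell, 0 rose and 2 did not pass (median -1.21, adjusted p = 2.2e-11, estimated 0.165), while list-wide 13 fell and 0 rose. In 34 proteasome genes in total RNA, 11 rose, 0 fell and 23 did not pass (median 0.37, adjusted p = 1.6e-05, estimated 0.508), and list-wide 17 rose and 0 fell. Relative calls numbered 520, 227 higher and 293 lower (22 fitted alone, 1491 blocked, where more of the S. pombe control passed, 200 and 90 without replicates 1 and 2), and spike-scaled calls 3433, 0 higher and 3433 lower (1551 without replicate 2, 695 when scaled by the brightest 25% of S. pombe genes and 292 fitted alone). In total RNA, HUG1 (2.15 ± 0.38), YAR068W, SER3 and ARG1 were higher and PHO5, FET3 (-2.76 ± 0.18), PRY1 and TIR3 lower, among 871 relative calls (57 fitted alone, 1407 blocked, 257 and 345 without replicates 1 and 2) and 18 spike-scaled calls, 7 higher and 11 lower (5 without either replicate).

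Strain spt8 had less TIR3 (-1.81 ± 0.30), the glucose-repressed alcohol dehydrogenase gene ADH2 (-1.77 ± 0.42), PRY1 (-1.72 ± 0.24), PRM7 and SPI1 in nascent RNA (n = 2 against 6), beside YLR154C-H and YLR157W-E on shared probes. DAD2 (1.48 ± 0.34), TMA10, SLF1, OPI10, KAP114, VHS3 and TBS1 rose by 0.90 to 1.48 (SLF1 0.67 blocked), as did IMA3. Of 25 ergosterol and mevalonate genes, 9 fell, 0 rose and 16 did not pass (median -0.46, adjusted p = 2.7e-06, estimated 0.346), and list-wide 14 fell and 0 rose. Among 19 glycolysis and fermentation genes, 2 fell, 0 rose and 17 did not pass (median -0.38, adjusted p = 0.00251, estimated 0.666, 0.139 blocked), as list-wide. In total RNA the glycine decarboxylase gene GCV3 (1.41 ± 0.10), TMA10 and the ribosomal protein genes RPL26A, RPS24B and RPS17B (1.05 to 1.21; 0.53 to 0.66 blocked) were higher, and PRM7 and AQR1 (-1.42 ± 0.23) lower, with YDR261C-D and YBL100W-A on shared probes. Of 128 cytosolic ribosomal protein genes, 69 rose, 0 fell and 59 did not pass (median 0.47, adjusted p = 1.5e-31, estimated 0.318), and list-wide 103 rose and 0 fell. Nascent relative calls numbered 472, 148 higher and 324 lower, a count that was 8 without replicate 1, 9 without replicate 2, 1 fitted alone and 1728 blocked. S. pombe genes, the negative control, passed at 13.5% against 11.6% here, and more often than here with that block, so these counts are not shown to come from the deletion. Spike-scaled, 3 genes passed in nascent RNA (SPT8, lower, among them) and 3 in total RNA (1 without either replicate), against 1389 and 10 blocked. Total relative calls were 474 (46 and 123 without replicates 1 and 2, 1135 blocked, and 0 fitted alone by limma, 436 unadjusted).

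Without both enzymes (ubp8_gcn5), PHO84 changed by -4.23 ± 0.29, VTC3 by -2.19 ± 0.15, the RNA exonuclease gene REX2 by -1.75 ± 0.11 and MFA1 by -1.65 ± 0.19 in nascent RNA (n = 4 against 6), and HO, BAR1 and PHO3 changed by -1.62 to -1.67, with HXT7 on shared probes. ARG1 rose by 3.45 ± 0.15 and SNZ1 of vitamin B6 synthesis by 2.64 ± 0.14, with AAD6, CIS1, OYE3, HSP26 and CRG1 at 2.20 to 3.12 (AAD6 2.05, CIS1 1.62 and OYE3 0.62 blocked), and THI13. The constants on these arrays step by 0.433 (log2), and with them undone PHO84 was -4.57, VTC3 -2.54, REX2 -2.09, MFA1 -1.99, ARG1 3.54 and SNZ1 2.73. Of 11 phosphate genes, 10 fell, 0 rose and 1 did not pass (median -1.37, adjusted p = 1.7e-11, estimated 0.0882), as list-wide. Among 5 selection marker genes in total RNA, 3 rose, 0 fell and 2 did not pass (median 0.44, adjusted p = 0.0300, estimated 0.455, called in 8 of 10 fits without 1 array), as list-wide. Relative calls were 1565, 983 higher and 582 lower (761 fitted alone, 615 averaged, 768 with replicate number as a block), against 1133 with the constants undone, 580 higher and 553 lower, and 647 higher and 795 lower with quantile normalization. Spike-scaled calls were 4006 (1591 with the constants undone), of which 4001 were lower. In total RNA, ARG1 (3.64 ± 0.32), CIS1, SNZ1 and AAD6 were higher, FRM2 was higher by 2.94 ± 1.07 but 0.58 and not past the threshold when blocked, and PHO84 (-5.31 ± 0.72), VTC3, MFA1, BAR1 and REX2 were lower. Total RNA had 1660 relative calls (890 fitted alone, 878 averaged) and 282 spike-scaled, 66 higher and 216 lower (1183 blocked, 78 without replicate 2).

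In spt3_gcn5, PHO84 changed by -5.30 ± 0.36, YRO2 by -4.57 ± 0.34, the NAD synthesis gene BNA1 by -4.04 ± 0.36, the secreted glycoprotein gene YGP1 by -4.04 ± 0.27 and PHO3 by -4.00 ± 0.22 in nascent RNA (n = 2 against 6). PUT1 of proline use rose by 2.66 ± 0.19 and SER3 by 2.36 ± 0.24, with ARG7, ICS3, SRL3, SMF3 and IZH3 at 2.21 to 2.38 (SMF3 1.27 and IZH3 1.31 blocked), of which PUT1, SRL3, SMF3 and IZH3 lie on chromosomes 11 and 12, whose genes were higher as a group. Batch as a block took YDR524W-C from 3.41 to 0.67, YCR102C from -4.21 to -1.13 and YLR460C from -3.98 to -0.56. Of 34 respiratory chain genes, 22 fell, 1 rose and 11 did not pass (median -0.90, adjusted p = 1.4e-05, estimated 0.465), as list-wide. Of 14 iron regulon genes, 9 rose, 0 fell and 5 did not pass (median 0.81, adjusted p = 6.7e-04, estimated 0.151, spike-scaled median -1.79), as list-wide. Among 27 heat shock protein and chaperone genes, 12 fell, 3 rose and 12 did not pass (median -0.54, adjusted p = 0.00957, estimated 0.747, 0.0512 blocked), while list-wide 13 fell and 3 rose. In 9 histone genes in total RNA, 8 fell, 0 rose and 1 did not pass (median -0.86, adjusted p = 0.0159, estimated 0.601, 0.0805 blocked), and list-wide 8 fell and 0 rose. Relative calls were 1877, 873 higher and 1004 lower (570 fitted alone, 1066 and 1064 without replicates 1 and 2), and spike-scaled calls 4050. In total RNA, SER3 (2.76 ± 0.35), PUT1, AYT1 and PLN1 (these 3 on chromosome 11 or 12) were higher and PHO84 (-4.99 ± 0.91), YLR460C and YCR102C lower, while YDR524W-C (3.13) and OYE3 (-4.51) did not pass with batch as a block (0.23 and -0.53). Total RNA gave 2282 relative (934 fitted alone) and 3652 spike-scaled calls, 11 higher and 3641 lower. The relative counts, 45.9 and 55.8% of genes, do not exceed the S. pombe control (53.6 and 56.6%), while blocked they do (1518 and 2007, or 37.2 and 49.1%, against 1.99 and 0.153%).

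What did a second deletion add to a single one? Against gcn5, ubp8_gcn5 had more nascent YIL014C-A (1.79 ± 0.42), YNL040W, SNZ1 (1.48 ± 0.16) and PRM7 and less TIP1 (-1.22 ± 0.14), PNC1 and AYR1, with HXT7 on shared probes (n = 4 against 4). Against ubp8 it had more ARG1 (3.05 ± 0.17), SNZ1, RTS3 and MUP1 and less PHO84 (-3.72 ± 0.31), TIP1, VTC3 and FSH1. The interaction, the double mutant's change minus the sum of both singles, was positive for THI7 (2.06 ± 0.14; 1.72 with the constants undone), PRM7, FYV7 and ALT2 and negative for PNC1 (-1.80 ± 0.23), STF2, DCS1 and RGI1. Relative calls were 715 against gcn5, 1182 against ubp8 and 629 for the interaction (344 without ubp8_gcn5 replicate 1), 142, 481 and 137 with the constants undone, 1432, 2019 and 849 blocked, 1202, 2361 and 279 fitted alone and 29, 231 and 1 averaged. Spike-scaled calls were 3912, 3970 and 2211, against 5, 201 and 0 with the constants undone (192 unadjusted for the last) and 4034, 4058 and 3900 blocked. Shifts of the median were -1.33 against gcn5 and -1.50 against ubp8 (exact p = 0.0286, adjusted p = 0.0571 for each), but -0.10 and -0.27 with the constants undone. In total RNA the shifts were -0.52 and -0.63 (exact adjusted p = 0.0571 each), with 274, 634 and 331 relative calls and 1 (TIP1, lower), 153 and 6 spike-scaled calls. Blocked, these were 968, 1429 and 781 relative and 16, 1665 and 17 spike-scaled calls. Relative ones were 68, 267 and 3 averaged, and without 1 array as few as 158, 459 and 175 relative and 0, 21 and 1 (up to 1322) spike-scaled.

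Against spt3, spt3_gcn5 had more nascent FET3 (3.79 ± 0.32; 3.54 blocked), SIT1, a siderophore transporter gene (3.57 ± 0.29; likewise 3.18) and IZH3 (2.76; 1.41, n = 2 against 2). GCV1 (2.86), FRM2 (-7.18) and OYE3 (-5.36) changed sign when blocked (-0.79, 0.37 and 0.42), and YLR460C and YCR102C were lower. Against gcn5, YDR524W-C (4.76; 0.64 and not past the threshold when blocked), SMF3 (2.95 ± 0.34; 1.45), MCH5 (2.56; 0.47, which did not pass) and IZH3 (1.16 with that block) were higher, OYE3 (-6.27; -0.49, which did not pass) and YCR102C (-5.89; -1.27) lower, and FRM2 turned from -7.35 to 0.20 with that block. The interaction was positive for SIT1 (4.13 ± 0.34), FET3 (3.88 ± 0.38) and MCH5 (not past the threshold when blocked), and YDR524W-C, FRM2 and OYE3 changed sign when blocked. Relative calls were 1608, 2128 and 1638 against spt3, against gcn5 and for the interaction (1384, 1306 and 1350 blocked, 972 and 1302 for the first pair without spt3_gcn5 replicates 2 and 1). Spike-scaled calls were 3243, 3929 and 1933 in nascent RNA (4032, 4085 and 3816 blocked, 904, 1859 and 358 by the brightest 25% of S. pombe genes) and 3189, 3763 and 3054 in total RNA (79, 1631 and 101 blocked), and total relative calls 2234, 2502 and 2332 (1476, 1672 and 1383 with that block). The nascent median lay -1.51 from spt3 and -2.14 from gcn5 (exact p = 0.333 and 0.0667, the smallest possible), and the total RNA median -1.51 and -1.84. These hold the batch difference, as spt3_gcn5 is in the second batch and the singles in the first. The second batch had higher nascent and lower total WT medians.

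Of single deletions, against spt8, spt3 had more nascent SER3 (2.81 ± 0.29), YAR068W and ARG1 and less FET3 (-2.58 ± 0.32), PHO84 and PHO5 (n = 2 against 2), in 41 calls (130 blocked, 11 without spt8 replicate 1) and 107 in total RNA. Against ubp8, gcn5 had more ARG1 (2.81 ± 0.17), RTS3, MUP1 and BAP2 and less PHO84 (-3.24 ± 0.31), ARR2 and YNL040W (n = 4 against 4), in 376 calls (979 blocked, 1046 fitted alone, 23 averaged, 197 without gcn5 replicate 2) and 383 in total RNA. In total RNA the arrays labelled spt20 lay above spt7 for CWP1 (2.36 ± 0.67), PHO84 (2.27 ± 0.79) and YER053C-A and below it for ARG1 (-2.68 ± 0.35) and ANB1, in 815 calls (256 averaged). Without spt20 total replicates 1 and 3, CWP1 was -0.0029, PHO84 -0.45 and ARG1 -1.53, in 401 calls.

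The nascent shift minus the total RNA shift was -1.76 in spt7 without the signal filter (exact adjusted p = 0.0762), where it was -2.21 and called with that filter (exact adjusted p = 0.0381), -1.53 in ubp8_gcn5 (0.0571) and -1.37 in spt20 (0.114; -0.66 without spt20 total replicates 1 and 3). With too few arrays to pass unless several shifts share the smallest p, the spt7 value with the filter stayed at -1.65 against WT arrays of the same batch, -2.39 to -1.98 without any 1 spt7 or WT nascent array and -2.18 with consecutive replicates averaged. With the constants undone the value was -0.45 in spt7 without the filter (-0.90 with it) and -0.29 in ubp8_gcn5. It was -1.01 in spt3, -1.01 in spt3_gcn5, -0.71 in gcn5, -0.66 in ubp8 and -0.39 in spt8 (0.25 without spike-in scaling), none of which passed. WT arrays of each strain's own batch, which differ between batches in this measure, gave -0.44 in spt3, -2.14 in spt3_gcn5, -0.15 in gcn5, -0.094 in ubp8, 0.18 in spt8, -0.96 in ubp8_gcn5 and -0.81 in spt20. By gene, CKS1 (-2.12 ± 0.53), PAU23 and GCV1 fell more in nascent RNA of ubp8_gcn5, in 3908 calls (0, and 1 unadjusted, with the constants undone). SUC2 (-2.30 ± 0.43), IDP1 and YDR042C did so in spt3_gcn5 (920 calls, 1628 with the culture as a random block, 0 without spt3_gcn5 total replicate 2 and 1765 without WT nascent replicate 3) and ANB1, CKS1 and SDD2 in spt3 (400 calls, 1641 with that block, 0 without WT total replicate 3 and 1698 without WT nascent replicate 3). For spt20, 3672 calls led by CWP1 (-3.09 ± 0.81), PHO84 and YER053C-A became 0 (469 unadjusted) without those 2 spt20 arrays. limma called 0 genes in ubp8, gcn5 and spt8, where 373, 620 and 575 had an unadjusted p below the threshold.

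Relative nascent changes were correlated across genes, which are not independent replicates, for the 21 pairs of strains. The highest were gcn5 and ubp8_gcn5 (r = 0.74), spt3 and spt8 (r = 0.67), spt20 and ubp8 (r = 0.65) and ubp8 and gcn5 (r = 0.64). Against WT arrays of each strain's own batch these were r = 0.75, 0.75, 0.44 and 0.54, and ubp8 with ubp8_gcn5 (0.54) and spt20 with spt3_gcn5 (0.48) and ubp8_gcn5 (0.45) lay above the third. The nascent spt3 and spt8 arrays and gcn5 replicate 2 also stood apart in S. pombe profile (rho with WT 3 to 6 of 0.907 to 0.923, others of the batch 0.954 to 0.978), so a technical part of the second r is not excluded. Simulated unchanged strains sharing the WT arrays gave r = 0.39, 0.26, 0.41 and 0.40, and separate groups of 3 WT arrays gave r = 0.62, 0.54, 0.55 and 0.50. The covariance exceeded the simulated one by 0.138, 0.101, 0.146 and 0.0908. The lowest was ubp8 and spt3_gcn5 (r = -0.44), which became r = 0.11 against WT arrays of each strain's own batch.

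S. pombe genes, which come from separate cells, served as a negative control (1305 genes tested after removal of each array's median). limma called 0 in spt20 of both fractions (301 and 293 at an unadjusted p below the threshold), 6 and 26 in ubp8, 17 and 30 in gcn5, 14 and 74 in ubp8_gcn5, 94 and 5 in spt3, 176 and 28 in spt8, and 41 in total RNA of spt7. In spt3_gcn5 it called 699 and 739, and 26 and 2 blocked, which raised the nascent counts of gcn5 to 451, of spt3 to 785 and of spt8 to 769 (34.6, 60.2 and 58.9%, against 35, 36.5 and 42.3% of S. cerevisiae genes), so blocked counts do not stand out there. The nascent change fell with WT signal in ubp8_gcn5 (rho = -0.58 across genes, -0.26 with the constants undone) and spt8 (rho = -0.41), and rho lay between -0.23 and 0.077 in the other strains.

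Genes were set out by chromosome (assembly R64) to find regions that moved together. In spt3_gcn5 the median relative change was 0.76 in both arrays for chromosome 11 and 0.80 to 0.86 for chromosome 12 in nascent RNA, and 0.77 to 0.78 and 0.83 to 0.84 in total RNA. Of the nascent genes, 165 of 239 on chromosome 11 and 256 of 367 on chromosome 12 rose, against 452 of 3480 elsewhere. Chromosome 3 of spt20 lay at 0.25 to 0.31 in nascent RNA, and no other chromosome lay beyond 0.2 in every array of a strain.

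**Figure D3:**
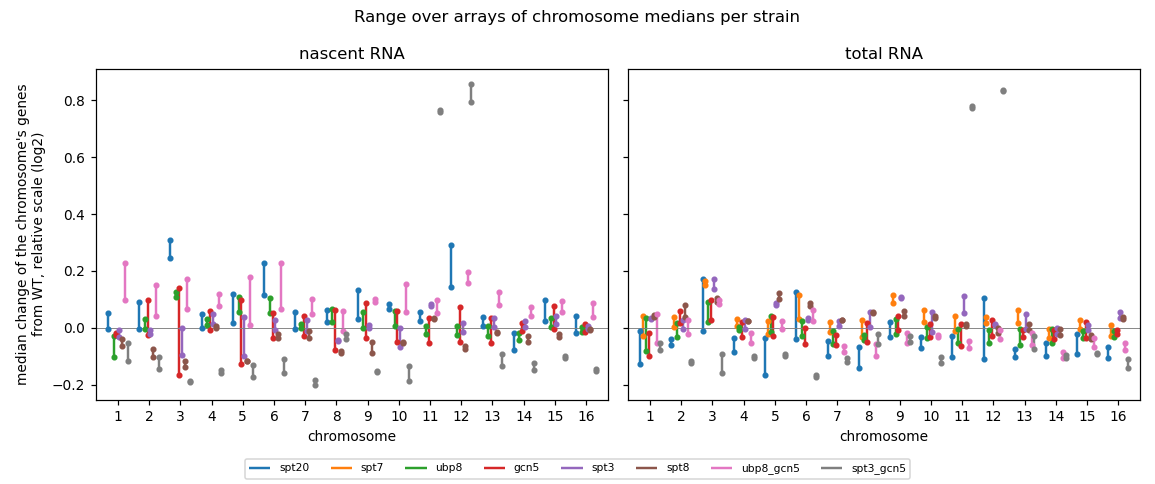
Median relative log2 change of the genes of each chromosome in each array, by strain and fraction. Chromosomes 11 and 12 of spt3_gcn5 lie between 0.76 and 0.86 in nascent RNA.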

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

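The splits of the samples were written before the results were seen. Tests of spt20 total replicates 1 and 3 and of the lower medians came after, and those of the chromosomes followed a pattern already seen.

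Genes of chromosomes 11 and 12 were higher in spt3_gcn5 as a group. An extra copy of both would raise each 25% of their genes by position in each array. The 32 such medians ran from 0.69 to 0.97, above a limit of 0.5 that the whole-chromosome medians made easy to pass. The array batch shared with WT replicates 7 and 8 is excluded, as the median of neither chromosome in these WT arrays against WT replicates 3 to 6 was above 0.19, and against them spt3_gcn5 lay at 0.72 to 0.82. An extra copy of both in the strain is therefore a candidate explanation, found and tested on the same data.

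The arrays labelled spt20 total replicates 1 and 3 carry SPT20 signal. A mislabelled sample could account for it, with no biological explanation tested, since their changes from WT rose with those of spt20 nascent RNA with slopes of only 0.18 and 0.19, against 0.99 and 0.98 in replicates 2 and 4, and their spread (SD 0.288 and 0.290) lies in the range of single WT arrays (0.199 to 0.292). A culture of deletion cells mixed with WT cells stays open, excluded only if equally numbered arrays share a culture, which mislabelling would break. SPT20 lay at -4.68 and -3.81 in spt20 nascent replicates 1 and 3 (-7.98 and -7.08 in 2 and 4) against 0.16 to 3.06 in WT, at best -3.97 from the lowest WT array (WT SD 1.29). Some WT material in nascent replicates 1 and 3 stays open, as nascent PHO84 lay nearer to WT (1.89 to 3.27) there too (-1.50 and -1.60, against -2.90 in both 2 and 4). A small share of deletion RNA that entered these 2 total RNA samples later was not tested, and TAT1 (-0.44 and -0.35) and MFA1 (-0.13 and -0.19) lay below their WT ranges (-0.25 to 0.29 and -0.098 to 0.12), while PHO84 (0.088 and 0.054) did not, and CWP1 (0.35 and 0.38) and HIS4 (0.56 and 0.47) lay above theirs (highest 0.095 and 0.30), opposite to replicates 2 and 4.

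The nascent medians of spt7 and ubp8_gcn5 lay below every WT array. A constant on the S. cerevisiae signals is undecided as the whole cause in spt7, where with it undone, and without the signal filter, 1 of 4 arrays (1.32) entered the WT range (lowest 1.20) and the others (0.67 to 0.87) did not. Less new RNA in spt7 could account for it and is undecided for that array, though it would fit by the mean alone, 0.90 (SD 0.287) and -0.30 from the lowest WT array, and the shift went from -2.21 to -0.90 (exact adjusted p = 0.143). A constant fits in ubp8_gcn5, where 2 of 4 arrays (1.64 and 1.51) entered the WT range (lowest 1.18) and the others (0.82 and 1.02) did not. Less new RNA in ubp8_gcn5 could account for part of it and is undecided, as the undone mean of 1.25 lay 0.065 above the lowest WT array, within the strain's SD (0.393), all by rules set after the values were seen.

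Single arrays stood apart in some groups, and the test used (Dixon) flags about 1 in 20 groups by chance. The median of spt20 nascent replicate 3 was 0.94 (others 0.57 to 0.60) and that of spt7 total replicate 4 was 0.72 (others 0.57 to 0.59), among 35 groups of medians and deleted genes. Of 306 sets of named-gene values, 12 had an array apart, 4 of them WT nascent replicate 6. The nascent minus total shift passed in spt7 at -2.21 with the signal filter (-1.76 without it did not), and at -1.53 in ubp8_gcn5 it lay outside WT with an exact adjusted p of 0.0571, and each is a difference between groups. Columns of WT nascent replicates 1 and 2, no part of the comparisons, hold S. cerevisiae signals at a median log2 ratio of 1.17 and 1.00 to the means of replicates 3 and 4 and of 5 and 6, whose S. pombe means they equal.

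Counts of groups of at least 4 arrays were set against those of 100 drawn splits of the same arrays (35 in all for 4 against 4), and are given as real count/highest other. Nascent spike-scaled counts were rare in spt20 (3456/3636) and ubp8_gcn5 (4006/3973) and not in ubp8 (6/3200) and gcn5 (717/3217). Nascent relative counts were rare in spt20 (1861/1798) and ubp8_gcn5 (1565/1974) and not in ubp8 (549/1752) and gcn5 (823/2045). Total spike-scaled counts were rare in spt7 (1136/2513) and not in spt20 (64/4012), ubp8 (31/1419), gcn5 (104/990) and ubp8_gcn5 (282/1674). Total relative counts were rare in spt7 (1810/2006) and ubp8_gcn5 (1660/1724) and not in spt20 (1556/2281), ubp8 (820/2075) and gcn5 (1314/2007). Between mutants (35 splits) counts were rare for ubp8_gcn5 minus gcn5 (3912/1980 spike-scaled, 715/204 relative) and ubp8_gcn5 minus ubp8 (3970/3446 spike-scaled, 1182/0 relative) in nascent RNA, ubp8_gcn5 minus gcn5 (274/2 relative) and ubp8_gcn5 minus ubp8 (153/0 spike-scaled, 634/0 relative) in total RNA, and gcn5 minus ubp8 (376/0) in nascent RNA. The 153 calls were 21 to 84 without 1 of these arrays. The count of spt20 minus spt7 (815/134) was rare as labelled, but the labels of spt20 total replicates 1 and 3 are in doubt, and without these arrays the count was 401, the CWP1 and PHO84 differences vanished or reversed, and 2 against 4 arrays give too few splits. The spike-scaled 1/0 of ubp8_gcn5 minus gcn5 in total RNA is 1 gene, which 7 of the 8 fits without 1 array of these strains lose, and is left open. For interactions of ubp8_gcn5, labels were drawn across WT, both singles and the double mutant, which also removes the effects of the single deletions. These draws therefore cannot decide whether an interaction is chance. The counts were 2211/3005 spike-scaled and 629/1756 relative in nascent RNA and 331/530 relative in total RNA. In spike-scaled total RNA they were 6/1854, and the 6 calls fall to 1 or 2 in 9 of 18 fits without 1 array. Between fractions the count was rare for ubp8_gcn5 (3908/3925) and not for spt20 (3672/3890), nor for ubp8 (0/2890) and gcn5 (0/3288), where limma called 0 and all 100 splits give as many. Splits that put WT replicates 7 and 8 together in the smaller group follow the array batch and gave as many genes as the real one in these cases, listed with the real split's count under batch as a block: nascent spike-scaled spt20 3306, ubp8 47, gcn5 500; nascent relative ubp8 480, gcn5 1432, ubp8_gcn5 2257; total spike-scaled spt20 31, ubp8 12, gcn5 101, ubp8_gcn5 1183; total relative spt20 1464, ubp8 897, gcn5 1816, ubp8_gcn5 2166; between fractions spt20 3822, ubp8 0, gcn5 0, ubp8_gcn5 3981. Without those splits the highest other count fell to 101 for nascent relative ubp8, 5 for total spike-scaled ubp8 and 0 for total spike-scaled gcn5. A split that calls several times the real count, such as 3200 against 6 in ubp8 or 4012 against 64 in spt20, points to a structure of the samples. All 4 nascent arrays of ubp8_gcn5 appear divided by constants, so no split can tell the constants from the strain, and with them undone the real counts are 1591 against WT, 5, 201 and 0 for the spike-scaled contrasts with gcn5 and ubp8 and the interaction, and 0 between fractions (limma, 192 and 1 unadjusted for the last pair). The splits treat arrays as independent. If the 4 arrays are repeats of the 2 cultures of the labels, they call counts rare too easily.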

How the results depend on the processing

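The alternatives given above as added later, and all tests of them, were chosen after the results were seen. The others were set before the data were examined. A count of genes was taken as kept when it stayed within 1.5 times, and a tested shift when it kept its direction and its side of the threshold. Where a value moved, the cause was not tested, unless fewer genes or fewer samples are named with it. Taking the mean of a gene's probe sets kept 96 of 96 results. The 401 values of named genes were the same in 4240 comparisons with an alternative outside the leaving out of single arrays and lost their call in 380, and lost it in 278 fits without 1 array, and each that changed sign is printed below.

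The share of higher calls moved by over 10 percentage points in these cases, given as higher/lower. Without spike-in scaling the nascent spike-scaled split went from 34/3422 to 312/1805 for spt20, 4/2 to 112/162 for ubp8, 27/690 to 189/396 for gcn5, 1/2 to 121/50 for spt8 and 11/1922 to 201/1370 for spt3_gcn5 interaction. Likewise the total spike-scaled split went from 59/5 to 690/573 for spt20, 32/1104 to 637/1088 for spt7, 31/0 to 331/223 for ubp8, 90/14 to 590/558 for gcn5, 7/11 to 196/683 for spt3, 2/1 to 140/142 for spt8, 66/216 to 557/1094 for ubp8_gcn5, 11/3641 to 408/2506 for spt3_gcn5, 0/1 to 71/220 for ubp8_gcn5 minus gcn5, 8/145 to 178/596 for ubp8_gcn5 minus ubp8, 7/3182 to 483/1905 for spt3_gcn5 minus spt3, 4/3759 to 394/2395 for spt3_gcn5 minus gcn5, 0/6 to 54/215 for ubp8_gcn5 interaction and 6/3048 to 506/1804 for spt3_gcn5 interaction. By the brightest 25% of S. pombe genes the nascent spike-scaled split went from 1/2 to 1/1 for spt8. Likewise the total spike-scaled split went from 7/11 to 6/49 for spt3, 2/1 to 1/2 for spt8, 66/216 to 95/972 for ubp8_gcn5 and 0/1 to 2/14 for ubp8_gcn5 minus gcn5. With quantile normalization the nascent relative split went from 148/324 to 151/210 for spt8, 983/582 to 647/795 for ubp8_gcn5, 568/147 to 219/216 for ubp8_gcn5 minus gcn5, 840/342 to 366/300 for ubp8_gcn5 minus ubp8 and 467/162 to 167/108 for ubp8_gcn5 interaction. Likewise the total relative split went from 295/179 to 82/107 for spt8. With constants undone the nascent spike-scaled split went from 0/3912 to 4/1 for ubp8_gcn5 minus gcn5. Likewise the nascent relative split went from 983/582 to 580/553 for ubp8_gcn5, 568/147 to 91/51 for ubp8_gcn5 minus gcn5, 840/342 to 263/218 for ubp8_gcn5 minus ubp8 and 467/162 to 71/66 for ubp8_gcn5 interaction.

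Without spike-in scaling, 42 of 66 results kept their direction and side or their count. Nascent spike-scaled counts became 2117 for spt20, 274 for ubp8, 461 for spt3, 171 for spt8, 2561 for spt3_gcn5, 1912 for spt3_gcn5 minus spt3 and 2237 for spt3_gcn5 minus gcn5. Total spike-scaled counts became 1263 for spt20, 1725 for spt7, 554 for ubp8, 1148 for gcn5, 879 for spt3, 282 for spt8, 1651 for ubp8_gcn5, 291 for ubp8_gcn5 minus gcn5, 774 for ubp8_gcn5 minus ubp8 and 269 for ubp8_gcn5 interaction. Nascent minus total gene counts became 871 for spt20, 0 for spt3, 16 for spt8 and 164 for spt3_gcn5. The shift between fractions passed at -1.35 for ubp8_gcn5. The total RNA shift changed sign to -0.021 for spt8. The nascent minus total shift changed sign to 0.25 for spt8.

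Scaling by the brightest 25% of S. pombe genes kept 47 of 66. It took nascent spike-scaled counts to 0 for ubp8, 84 for gcn5, 695 for spt3, 904 for spt3_gcn5 minus spt3, 1859 for spt3_gcn5 minus gcn5, 599 for ubp8_gcn5 interaction and 358 for spt3_gcn5 interaction. It took total spike-scaled counts to 112 for spt20, 159 for gcn5, 55 for spt3, 1067 for ubp8_gcn5, 16 for ubp8_gcn5 minus gcn5, 692 for ubp8_gcn5 minus ubp8, 16 for ubp8_gcn5 interaction and 1972 for spt3_gcn5 interaction. It took nascent minus total gene counts to 0 for spt3 and 0 for spt3_gcn5. The nascent shift no longer passed at -2.03 for ubp8_gcn5. The total RNA shift passed at -0.52 for spt7. Quantile normalization kept 26 of 30. Nascent relative counts became 435 for ubp8_gcn5 minus gcn5, 666 for ubp8_gcn5 minus ubp8 and 275 for ubp8_gcn5 interaction. Total relative counts became 189 for spt8.

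Testing every gene kept 77 of 96. Then nascent spike-scaled counts were 24 for ubp8, 1188 for gcn5 and 19 for spt8. It took nascent relative counts to 2425 for ubp8_gcn5 and 1099 for ubp8_gcn5 minus gcn5. Then total spike-scaled counts were 238 for spt20, 169 for ubp8, 394 for gcn5, 36 for spt3, 7 for spt8, 541 for ubp8_gcn5, 10 for ubp8_gcn5 minus gcn5 and 10 for ubp8_gcn5 interaction. It took total relative counts to 509 for ubp8_gcn5 minus gcn5 and 1003 for ubp8_gcn5 minus ubp8. Then nascent minus total gene counts were 2226 for spt3, 5 for spt8 and 1909 for spt3_gcn5. The shift between fractions no longer passed at -1.76 for spt7. Leaving out the lower 50% of genes by signal kept 54 of 96, and part of what moved follows from fewer genes tested. This moved nascent spike-scaled counts to 2 for ubp8, 223 for gcn5, 1813 for spt3, 0 for spt8, 2682 for spt3_gcn5, 1935 for spt3_gcn5 minus spt3, 2513 for spt3_gcn5 minus gcn5 and 1101 for spt3_gcn5 interaction. Then nascent relative counts were 322 for ubp8, 525 for gcn5, 323 for spt3, 210 for spt8, 698 for ubp8_gcn5, 1206 for spt3_gcn5, 127 for ubp8_gcn5 minus gcn5, 325 for ubp8_gcn5 minus ubp8, 134 for ubp8_gcn5 interaction, 23 for spt3 minus spt8 and 189 for gcn5 minus ubp8. This moved total spike-scaled counts to 36 for spt20, 11 for ubp8, 9 for spt3, 1 for spt8, 2378 for spt3_gcn5, 10 for ubp8_gcn5 minus gcn5, 574 for ubp8_gcn5 minus ubp8, 1990 for spt3_gcn5 minus spt3, 2440 for spt3_gcn5 minus gcn5, 24 for ubp8_gcn5 interaction and 1889 for spt3_gcn5 interaction. Then total relative counts were 1111 for spt7, 525 for ubp8, 833 for gcn5, 1046 for ubp8_gcn5, 137 for ubp8_gcn5 minus gcn5, 385 for ubp8_gcn5 minus ubp8, 201 for ubp8_gcn5 interaction and 510 for spt20 minus spt7. This moved nascent minus total gene counts to 2390 for spt20, 0 for spt3, 2589 for ubp8_gcn5 and 245 for spt3_gcn5.

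Averaging consecutive replicate numbers kept 46 of 96, and what moved follows at least in part from fewer samples. It leaves 1 value each of spt3, spt8 and spt3_gcn5, so counts with these strains rest on the spread of the other groups and say nothing about how stable they are. Nascent spike-scaled counts here were 0 for ubp8, 9 for gcn5, 545 for spt3, 1 for spt8, 2127 for spt3_gcn5 minus spt3, 576 for ubp8_gcn5 interaction and 831 for spt3_gcn5 interaction. This moved nascent relative counts to 770 for spt20, 1 for ubp8, 142 for gcn5, 35 for spt3, 1 for spt8, 615 for ubp8_gcn5, 672 for spt3_gcn5, 29 for ubp8_gcn5 minus gcn5, 231 for ubp8_gcn5 minus ubp8, 355 for spt3_gcn5 minus spt3, 691 for spt3_gcn5 minus gcn5, 1 for ubp8_gcn5 interaction, 226 for spt3_gcn5 interaction, 7 for spt3 minus spt8 and 23 for gcn5 minus ubp8. Total spike-scaled counts here were 31 for spt20, 0 for ubp8, 42 for spt3, 1 for spt8, 808 for ubp8_gcn5, 720 for ubp8_gcn5 minus gcn5, 1445 for ubp8_gcn5 minus ubp8 and 0 for ubp8_gcn5 interaction. This moved total relative counts to 449 for spt20, 985 for spt7, 112 for ubp8, 574 for gcn5, 245 for spt3, 11 for spt8, 878 for ubp8_gcn5, 1353 for spt3_gcn5, 68 for ubp8_gcn5 minus gcn5, 267 for ubp8_gcn5 minus ubp8, 1121 for spt3_gcn5 minus spt3, 1539 for spt3_gcn5 minus gcn5, 3 for ubp8_gcn5 interaction, 1148 for spt3_gcn5 interaction and 256 for spt20 minus spt7. Nascent minus total gene counts here were 0 for spt3 and 0 for spt3_gcn5. The nascent shift no longer passed at -2.73 for spt7 and -1.78 for ubp8_gcn5, nor the nascent minus total shift at -2.18 for spt7.

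An intensity trend in limma kept 63 of 64. Total spike-scaled counts became 2 for ubp8_gcn5 minus gcn5. Fitting only the groups compared kept 25 of 64, with fewer samples to estimate the spread. Nascent spike-scaled counts became 0 for ubp8, 25 for gcn5, 292 for spt3 and 1 for spt8. Nascent relative counts here were 942 for spt20, 39 for ubp8, 198 for gcn5, 22 for spt3, 1 for spt8, 761 for ubp8_gcn5, 570 for spt3_gcn5, 1202 for ubp8_gcn5 minus gcn5, 2361 for ubp8_gcn5 minus ubp8, 279 for ubp8_gcn5 interaction, 728 for spt3_gcn5 interaction, 157 for spt3 minus spt8 and 1046 for gcn5 minus ubp8. It took total spike-scaled counts to 0 for spt20, 1717 for spt7, 0 for ubp8, 0 for spt8, 709 for ubp8_gcn5, 3252 for ubp8_gcn5 minus gcn5, 3393 for ubp8_gcn5 minus ubp8 and 2476 for ubp8_gcn5 interaction. Total relative counts here were 7 for spt20, 1036 for spt7, 93 for ubp8, 499 for gcn5, 57 for spt3, 0 for spt8, 890 for ubp8_gcn5, 934 for spt3_gcn5, 1450 for ubp8_gcn5 minus gcn5, 2074 for ubp8_gcn5 minus ubp8 and 192 for ubp8_gcn5 interaction. Nascent minus total gene counts became 0 for spt20, 0 for spt3 and 0 for spt3_gcn5. With an estimated correlation in place of the preset 0.01, camera called 2 lists in nascent RNA of gcn5 and 0 in each other strain and fraction. Profile correlations over separate groups of 3 WT arrays kept 13 of 21, with fewer samples in each. Profile correlations became 0.55 for spt20 and ubp8, 0.021 for spt20 and spt8, 0.016 for ubp8 and spt8, -0.46 for ubp8 and spt3_gcn5, 0.62 for gcn5 and ubp8_gcn5, 0.54 for spt3 and spt8, 0.26 for spt3 and ubp8_gcn5 and -0.046 for spt8 and spt3_gcn5.

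With WT replicates 1 and 2 included as deposited, 81 of 96 kept theirs. It took nascent spike-scaled counts to 228 for ubp8, 1876 for gcn5, 12 for spt8, 1154 for ubp8_gcn5 interaction and 1225 for spt3_gcn5 interaction. Then total spike-scaled counts were 1709 for spt7, 588 for ubp8_gcn5, 4 for ubp8_gcn5 minus gcn5 and 504 for ubp8_gcn5 minus ubp8. It took nascent minus total gene counts to 1858 for spt3 and 1841 for spt3_gcn5. The nascent shift passed at -1.35 for spt20. The shift between fractions passed at -1.51 for spt20 and -1.67 for ubp8_gcn5. The nascent shift changed sign to -0.020 for spt8. With the constants undone, 17 of 28 kept theirs. Then nascent spike-scaled counts were 1591 for ubp8_gcn5, 5 for ubp8_gcn5 minus gcn5, 201 for ubp8_gcn5 minus ubp8 and 0 for ubp8_gcn5 interaction. Nascent relative counts became 142 for ubp8_gcn5 minus gcn5, 481 for ubp8_gcn5 minus ubp8 and 137 for ubp8_gcn5 interaction. Then nascent minus total gene counts were 0 for ubp8_gcn5. The nascent shift no longer passed at -1.43 for spt7 and -0.56 for ubp8_gcn5. The nascent minus total shift no longer passed at -0.90 for spt7. With both that and no signal filter, in spt7 alone, 1 of 3 kept theirs. Its shifts in nascent RNA (-0.90) and between fractions (-0.45) no longer passed.

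With the S. pombe profile batch as a block, 45 of 94 stayed within 1.5 times. This moved nascent spike-scaled counts to 47 for ubp8, 1389 for spt8, 3900 for ubp8_gcn5 interaction and 3816 for spt3_gcn5 interaction. It took nascent relative counts to 1432 for gcn5, 1491 for spt3, 1728 for spt8, 1432 for ubp8_gcn5 minus gcn5, 2019 for ubp8_gcn5 minus ubp8, 1306 for spt3_gcn5 minus gcn5, 130 for spt3 minus spt8 and 979 for gcn5 minus ubp8. This moved total spike-scaled counts to 31 for spt20, 2573 for spt7, 12 for ubp8, 29 for spt3, 10 for spt8, 1183 for ubp8_gcn5, 16 for ubp8_gcn5 minus gcn5, 1665 for ubp8_gcn5 minus ubp8, 79 for spt3_gcn5 minus spt3, 1631 for spt3_gcn5 minus gcn5, 17 for ubp8_gcn5 interaction and 101 for spt3_gcn5 interaction. Total relative counts became 1407 for spt3, 1135 for spt8, 968 for ubp8_gcn5 minus gcn5, 1429 for ubp8_gcn5 minus ubp8, 1476 for spt3_gcn5 minus spt3, 781 for ubp8_gcn5 interaction, 1383 for spt3_gcn5 interaction and 1736 for spt20 minus spt7. This moved nascent minus total gene counts to 1466 for spt3 and 1450 for spt3_gcn5. It took calls among the gene lists in total RNA to 14 for spt3 and 12 for ubp8_gcn5. S. pombe counts in nascent RNA became 29 for ubp8, 451 for gcn5, 785 for spt3, 769 for spt8, 45 for ubp8_gcn5 and 26 for spt3_gcn5. S. pombe counts in total RNA became 489 for spt7, 141 for ubp8, 219 for gcn5, 183 for spt3, 250 for spt8, 166 for ubp8_gcn5 and 2 for spt3_gcn5. Signs changed for nascent spike-scaled values of IZH3 -1.04 and PUT1 -0.17 for spt3_gcn5 minus spt3, of YDR524W-C -2.44 for spt3_gcn5 minus gcn5, of MCH5 -1.69 and SMF3 -1.01 for spt3_gcn5 interaction. Signs changed for nascent relative values of GCV1 -0.79, FRM2 0.37 and OYE3 0.42 for spt3_gcn5 minus spt3, of FRM2 0.20 for spt3_gcn5 minus gcn5, of YDR524W-C -1.50, FRM2 0.11 and OYE3 0.13 for spt3_gcn5 interaction. Signs changed for total spike-scaled YDR524W-C to -0.72 for spt3_gcn5 minus spt3, -0.84 for spt3_gcn5 minus gcn5 and -0.69 for spt3_gcn5 interaction. Signs changed for total relative values of FRM2 0.62 and OYE3 0.38 for spt3_gcn5 minus spt3, of FRM2 0.58 for spt3_gcn5 minus gcn5, of FRM2 0.42 and OYE3 0.035 for spt3_gcn5 interaction. The median of the cytosolic ribosomal protein list in nascent RNA of gcn5 turned to 0.035.

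Against WT arrays of the same batch alone, 28 of 45 kept theirs. It took profile correlations to 0.44 for spt20 and ubp8, 0.26 for spt20 and spt3, 0.016 for spt20 and spt8, 0.48 for spt20 and spt3_gcn5, 0.073 for ubp8 and spt8, 0.21 for gcn5 and spt3_gcn5, 0.23 for spt3 and spt3_gcn5, -0.047 for spt8 and spt3_gcn5 and 0.18 for ubp8_gcn5 and spt3_gcn5. The nascent shift no longer passed at -2.43 for spt7 and -1.48 for ubp8_gcn5. The nascent minus total shift no longer passed at -1.65 for spt7. The nascent shift changed sign to 0.016 for ubp8. The total RNA shift changed sign to -0.014 for spt20 and -0.0033 for gcn5. The shift between fractions changed sign to 0.18 for spt8. Then profile correlations were 0.11 for ubp8 and spt3_gcn5. Without the arrays labelled spt20 total replicates 1 and 3, 4 of 8 kept theirs. Total spike-scaled counts here were 2196 for spt20. It took total relative counts to 401 for spt20 minus spt7. Nascent minus total gene counts here were 0 for spt20. The total RNA shift changed sign to -0.57 for spt20. The spt20 minus spt7 values turned to CWP1 -0.0029 and PHO84 -0.45. Nascent minus total spt20 values turned to CWP1 0.079 and PHO84 0.54.

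Leaving out each array in turn gave these extremes, with the strain and replicate left out in parentheses and fewer samples per fit. The nascent shift ran from -2.89 (spt7 2) to -2.61 (WT 7) for spt7 and -1.92 (WT 3) to -1.66 (ubp8_gcn5 3) for ubp8_gcn5. Both calls (exact adjusted p = 0.0635 to 0.0762), and that of spt7 between fractions (0.0571 to 0.0635), were lost in these fits, where too few arrays are left to pass unless several shifts share the smallest p. The total RNA shift ran from -0.13 (spt20 3) to 0.53 (spt20 4) for spt20 and -0.19 (WT 7) to 0.018 (WT 6) for spt3. The nascent minus total shift ran from -2.39 (WT nascent 5) to -1.98 (WT nascent 7) for spt7. Nascent spike-scaled counts ran from 0 (ubp8 2) to 157 (WT 5) for ubp8, 266 (gcn5 3) to 1659 (WT 3) for gcn5, 1551 (spt3 2) to 3749 (WT 3) for spt3 and 1 (spt8 1) to 9 (WT 6) for spt8. Nascent relative counts ran from 224 (ubp8 4) to 1026 (WT 4) for ubp8, 90 (spt3 2) to 688 (WT 6) for spt3, 8 (spt8 1) to 606 (WT 6) for spt8, 1064 (spt3_gcn5 2) to 2269 (WT 7) for spt3_gcn5, 972 (spt3_gcn5 2) to 1073 (spt3 2) for spt3_gcn5 minus spt3, 1302 (spt3_gcn5 1) to 2180 (gcn5 2) for spt3_gcn5 minus gcn5, 344 (ubp8_gcn5 1) to 914 (gcn5 2) for ubp8_gcn5 interaction, 11 (spt8 1) to 17 (spt3 1) for spt3 minus spt8 and 197 (gcn5 2) to 288 (gcn5 1) for gcn5 minus ubp8. Total spike-scaled counts ran from 41 (WT 7) to 390 (spt20 4) for spt20, 566 (spt7 1) to 1495 (WT 7) for spt7, 4 (ubp8 2) to 110 (WT 6) for ubp8, 49 (gcn5 2) to 220 (WT 6) for gcn5, 5 (spt3 1) to 19 (WT 4) for spt3, 1 (spt8 1) to 7 (WT 5) for spt8, 78 (ubp8_gcn5 2) to 309 (WT 7) for ubp8_gcn5, 0 (gcn5 1) to 1 (ubp8_gcn5 1) for ubp8_gcn5 minus gcn5, 21 (ubp8_gcn5 3) to 84 (ubp8 1) for ubp8_gcn5 minus ubp8 and 1 (gcn5 3) to 1322 (WT 6) for ubp8_gcn5 interaction. Total relative counts ran from 495 (ubp8 3) to 1200 (WT 4) for ubp8, 257 (spt3 1) to 1158 (WT 4) for spt3, 46 (spt8 1) to 607 (WT 4) for spt8, 158 (gcn5 2) to 233 (gcn5 1) for ubp8_gcn5 minus gcn5, 175 (ubp8_gcn5 2) to 456 (WT 6) for ubp8_gcn5 interaction and 414 (spt20 1) to 1024 (spt20 4) for spt20 minus spt7. Nascent minus total gene counts ran from 2415 (spt20 total 3) to 3918 (spt20 total 4) for spt20, 0 (WT total 3) to 1698 (WT nascent 3) for spt3, 0 (WT total 3) to 1 (spt8 total 2) for spt8 and 0 (spt3_gcn5 total 2) to 1765 (WT nascent 3) for spt3_gcn5.

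Between fractions, same-numbered arrays deviated together in WT (mean correlation 0.77, lowest 0.56), ubp8 (0.44, lowest 0.35) and spt20 (0.24, lowest 0.11), while gcn5 (0.023, lowest -0.31) and ubp8_gcn5 (-0.016, lowest -0.13) had pairs that did not, and spt3_gcn5, spt8 and spt3 had a correlation of 0.16, 0.0032 and -0.034. Between strains, every correlation was above 0.1 in 5 of 25 nascent and 2 of 33 total RNA comparisons. The fractions of a culture had a consensus correlation of 0.169. With the replicate number as a block, 20 of 45 stayed within 1.5 times. Nascent spike-scaled counts here were 165 for spt20, 335 for ubp8 and 3896 for ubp8_gcn5 interaction. Then nascent relative counts were 202 for spt20, 52 for ubp8, 768 for ubp8_gcn5, 1095 for ubp8_gcn5 minus gcn5, 2441 for ubp8_gcn5 minus ubp8, 1320 for spt3_gcn5 minus gcn5, 532 for spt3 minus spt8 and 945 for gcn5 minus ubp8. Total spike-scaled counts became 0 for spt20, 2804 for spt7, 856 for ubp8, 711 for gcn5, 1695 for ubp8_gcn5, 2936 for ubp8_gcn5 minus gcn5, 3466 for ubp8_gcn5 minus ubp8 and 2985 for ubp8_gcn5 interaction. Then total relative counts were 34 for spt20, 1263 for ubp8_gcn5 minus gcn5, 1973 for ubp8_gcn5 minus ubp8, 1031 for ubp8_gcn5 interaction and 168 for spt20 minus spt7. Nascent minus total gene counts became 6 for spt20. With the culture as a random block, 5 of 7 stayed within 1.5 times. It took nascent minus total gene counts to 1641 for spt3 and 1628 for spt3_gcn5.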

Other observations

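Members of the transcription machinery were not called as a group in any strain without a batch term, and each list is given where its adjusted p was lowest, that of SAGA without the genes deleted in a strain (0.234 in nascent RNA of spt3_gcn5, 0.0646 with SPT3). These were 17 genes of SAGA subunits (ubp8 nascent RNA, median -0.15, 0 rose and 0 fell, alone 0 and 0, adjusted p = 0.111), 9 genes of TFIID-specific subunits (spt8 nascent RNA, median 0.19, 0 rose and 0 fell, alone 0 and 0, adjusted p = 0.111) and 51 genes of RNA polymerase II, its general factors and Mediator (spt3_gcn5 total RNA, median -0.41, 10 rose and 27 fell, alone 11 and 28, adjusted p = 0.0861). Likewise 31 mRNA decay genes (ubp8 total RNA, median -0.077, 1 rose and 7 fell, alone 1 and 9, adjusted p = 0.0599) and 7 galactose and glucose-repressed genes (spt8 nascent RNA, median -0.37, 0 rose and 2 fell, alone 0 and 2, adjusted p = 0.0764) did not pass. The counts alone are those adjusted over the list, and spike-scaled medians have the opposite sign for mRNA decay genes (0.28). With batch as a block, and at the preset correlation of genes, those of RNA polymerase II, general factors and Mediator passed as lower in total RNA of ubp8, ubp8_gcn5, gcn5 and spt8 and in nascent RNA of ubp8 (adjusted p = 3.5e-04, 0.00399, 0.00617, 0.0305 and 0.0103). So did mRNA decay genes in nascent and total RNA of ubp8 (0.0404 and 0.0232) and SAGA subunits in nascent RNA of ubp8 (0.0228), while galactose and glucose-repressed genes passed as higher in total RNA of spt7 and ubp8 (0.0284 and 0.0232). At an estimated correlation, not tried with the block, none was called, and with the block 10.8 to 37.5% of S. pombe genes passed in these total RNA comparisons.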
